A study of Homo sapiens with 8 samples.

How the data were processed

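RNA was sequenced from 92.1 cells, an established human uveal melanoma cell line, after 24 h with vehicle (DMSO), 10 nM trametinib, 10 nM panobinostat or both drugs. The 4 groups had 2 libraries each, 8 in all. Trametinib inhibits the kinases MEK1 and MEK2, and panobinostat inhibits histone deacetylases. The treatment label of the panobinostat libraries names the drug and also calls it a MEK inhibitor. The drug name was followed here. The label of the combination libraries gives 10 nM once for both drugs, and that each was used at 10 nM is an assumption on which the interaction and the comparisons with the single drugs rest. Per the labels' protocols, libraries were made from total RNA with the NuGEN Ovation Human FFPE RNA-Seq kit. Whether reads were counted by strand is not given in the sources used here.

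The deposited table held 1 normalised signal value per gene and library for 18406 gene symbols, of which 458 were at 0 in all libraries. Per the submitters' processing notes, the tools were TopHat2 2.0.13, Cufflinks 2.2.1 and DESeq2, whose version is not given in the sources used here. The notes list genome build hs37d5 for the 4 vehicle and trametinib libraries and none for the other 4, and the gene annotation is not given in the sources used here. Within each library, the values were whole multiples of a fixed step. Dividing by that step gave whole reads for 100% of the values within a tolerance of 1e-06, so the deposited signal values were counts divided by a size factor. The recovered totals ran from 6897784 to 16861001 reads per library, and 1 read was worth between 0.602 and 1.52 in the deposited unit. No coordinates are printed, and symbols are those of the table.

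The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with an intensity trend, so low values understate changes and a single 0 can inflate them. All 8 libraries entered 1 fit with 4 residual and 5.32 prior degrees of freedom. The 13320 genes with a mean value of at least 10 were tested, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so the gene tests rest on the spread pooled over all groups. No source states that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The comparisons were each treatment against vehicle, the combination against each single drug, and the interaction. The interaction is the change from trametinib to the combination minus the change from vehicle to panobinostat, all in log2. Replicate numbers did not pair the libraries, and the fit had no block.

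Folds against a group whose libraries were both at 0 are lower bounds against a floor of 3 reads per library. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. Where a molecule was read many times, as may hold for trametinib replicate 2, the fold can be smaller than the bound. Histone, HLA, heat shock and tubulin genes have near-identical copies, and the counting may have split their reads, so single members of these families are uncertain. The same holds for overlapping and antisense genes where strand was not used.

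The 32 gene lists, the cell type markers, the named gene rule, the tests and a set of alternative settings were fixed before the data were examined. The lists were ERK pathway output, YAP/TEAD targets, receptor tyrosine kinases, PI3K/AKT components, G alpha q components, pigmentation and melanocyte lineage, mitosis, DNA replication, CDK inhibitors, the BCL2 family and p53 targets. Further lists were replication-dependent histones, histones with polyadenylated transcripts, histone deacetylases, acetyltransferases with BET proteins, neuronal genes, MHC class I, MHC class II, interferon-stimulated genes, and mesenchymal and matrix genes. The remaining lists were cholesterol synthesis, lysosome, glycolysis, unfolded protein and integrated stress response, heat shock, metallothioneins, nucleolar ribosome biogenesis, cytosolic ribosomal proteins, uveal melanoma class 1 and class 2 markers, cancer-testis genes and mitochondrially encoded RNAs. They held 571 entries, of which 526 were in the table and 467 were tested. Lists with at least 3 measured members, 28 in all, were tested against all other genes with limma's camera at a preset correlation of 0.01. Their p-values were adjusted by Benjamini-Hochberg over the lists within a comparison. The same test was run with an estimated correlation.

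Named genes passed the threshold, had a mean of at least 50 in the higher group and had no overlap between the libraries of the groups compared. Symbols of clones, small RNAs, antisense RNAs and ribosomal protein genes were left out of the ranking. The 10 largest rises and 10 largest falls were taken per comparison, and 5 each in the interaction. Up to 4 members of each list with the smallest adjusted p were added. DUSP6, SPRY4, ETV5, CCND1, CDKN1A, HDAC1, HDAC2, HDAC3, MAP2K1, MAP2K2, MITF, ROR1, IGF1R, YAP1, GNAQ, GNA11 and BAP1 were taken in every comparison.

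The procedure was tested on data simulated from the recovered reads, with 13320 genes, 100 changed 2-fold and 100 changed 4-fold. For trametinib against vehicle, limma recovered 67% of the 2-fold and 81% of the 4-fold changes and called 99 of 13120 unchanged genes, 40.1% of its calls, where edgeR called 110, DESeq2 215 and group weights 35. For panobinostat against vehicle it recovered 44% and 70%, with 0 false calls by limma, edgeR and DESeq2 and 7 with group weights. For the combination it recovered 53% and 72% against vehicle, 59% and 88% against trametinib, and 53% and 82% against panobinostat. Among 13120 unchanged genes there were 112 false calls against trametinib by limma, 43.2% of its calls, 103 by edgeR, 235 by DESeq2 and 26 with group weights. Against vehicle and against panobinostat, limma, edgeR and DESeq2 made 0 false calls, and group weights made 11 and 9. For the interaction it recovered 39% and 62%, with 6 false calls, 5.61% of its calls, against 11 by edgeR, 37 by DESeq2 and 18 with group weights. A changed list of 20 genes was found in each of the 6 contrasts by camera, and 0 of 27 random lists were called.

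The alternative settings fixed then were TMM and total-count rescaling, pseudocounts of 5 and 0.5, no filter, a mean of at least 50, a fit of only the 4 libraries compared, a replicate block, robust moderation, a log2 change of at least 1 and each library left out in turn. On the recovered reads, the quasi-likelihood test of edgeR 4.0.16 and DESeq2 1.42.0 were run as well. Of the 13320 genes, edgeR called 6804 for trametinib, 4286 for panobinostat and 6772 for the combination against vehicle. Alternatives chosen after the data were seen were a mean of at least 500, group weights from the spread of each group, and resampling of every library but trametinib replicate 2 to the multiplicity of that library. The multiplicity was 23, the peak of the number of genes per read number averaged over 5 neighbouring read numbers. The unaveraged peak from 3 reads up, 21, was a further alternative chosen after the data were seen, and it entered only the weighing of patterns. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. The 4 lists with fewer than 3 measured members were not tested as lists. Results for 2 single genes are not reported here.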

Results

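RNA sequencing measured expression in 92.1 uveal melanoma cells after 24 h with vehicle, 10 nM trametinib, 10 nM panobinostat or both, in 2 libraries per group. The series addressed whether inhibiting histone deacetylases adds to MEK inhibition in this tumour. The recovered reads per library were 16861001 and 12808244 in vehicle, 10342369 and 10528784 with trametinib, 10005164 and 10169082 with panobinostat, and 9017593 and 6897784 in the combination. Across the 13320 tested genes, replicates correlated at r = 0.991 in vehicle, 0.897 with trametinib, 0.982 with panobinostat and 0.974 in the combination, on the log2(value + 1) scale. Against the counting of independent reads, which the reads of amplified molecules are not, the chi-square per degree of freedom between replicates ran from 3.43 in vehicle to 17.5 with trametinib. The first principal component, 47.2% of the variance, placed both trametinib libraries (50.8 and 142) above the other 6, which lay between -49.3 and -2.87.

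The trametinib libraries differed from the rest, and from each other, at low read numbers. Trametinib replicate 2 had 5362 genes at 0 of the 18406 in the table and trametinib replicate 1 had 3743, against 2222 to 2890 in the other 6 libraries. Genes with 1 to 5 reads made up 2.10% of the detected genes in trametinib replicate 2, 6.74% in replicate 1 and between 9.93% and 13.3% elsewhere. Of 1104 genes with a vehicle value of 40 to 80, 11.1% were at 0 in trametinib replicate 2 and 1.18% in replicate 1.

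**Figure D1:**
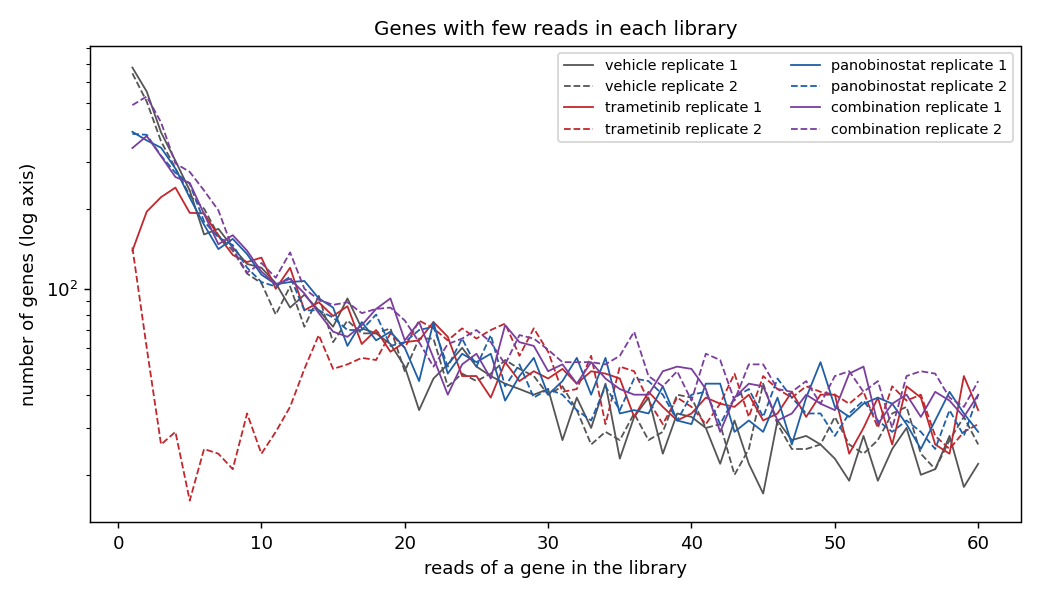
Number of genes (log axis) with each read number from 1 to 60, as 1 line per library. Trametinib replicate 2 (dashed red) has few genes with 3 to 10 reads. Averaged over 5 neighbouring read numbers, its curve peaks at 23 (21 without averaging, from 3 reads up), that of trametinib replicate 1 at 4 and those of the other 6 libraries at 3, the lowest this average can give.

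Trametinib against vehicle shows what blocking MEK does to these cells. Transcripts that depend on ERK activity fell, those of DNA replication, mitosis and ribosome biogenesis fell with them, and pigmentation genes rose. DUSP6, a phosphatase acting on ERK, was at 577 and 567 in vehicle, 190.0-fold above the floor, and at 0 in both trametinib libraries. DCT, a melanin synthesis enzyme, was at 14.4 and 4.75 in vehicle and 1984 and 1912 with trametinib. By limma, 3153 of 13320 genes rose and 3644 fell, 51.0% of those tested, and 1411 rose and 2022 fell by at least 2-fold.

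Of 21 measured genes of ERK pathway output, 0 rose and 18 fell, with 3 not passing (0 and 18 adjusted over the list alone, median -3.39, camera adjusted p = 1.24e-08). The feedback inhibitors SPRY4 and SPRY2 changed by -8.68 ± 0.44 and -8.14 ± 0.54 (log2 change ± SE, limma adjusted p = 4.09e-07 and 2.11e-06). CCND1, which encodes cyclin D1, changed by -3.35 ± 0.10, DUSP4 by -3.13 ± 0.087, and the ETS factors ETV4 and ETV5 by -5.56 ± 0.25 and -3.71 ± 0.25. SH3TC2 and MYO3A were also among the 10 largest falls, SH3TC2 at -8.61 ± 0.47 and MYO3A 52.9-fold lower against the floor of 3 reads per library.

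All 25 measured mitosis genes and all 30 DNA replication genes fell, also adjusted over the list alone (median log2 change -3.51 and -3.10, camera adjusted p = 4.42e-15 and 8.26e-14). MKI67, a proliferation marker, changed by -5.16 ± 0.12, and MCM3 of the replicative helicase by -2.85 ± 0.10. The kinesin KIF20B changed by -6.77 ± 0.99, the replication factor CDC45 by -7.04 ± 1.26, E2F2 by -6.75 ± 0.92 and C11orf82 by -7.05 ± 1.19. CDC45, E2F2, C11orf82 and HIST1H4C (-7.01 ± 1.26) were at 0 in trametinib replicate 2, with trametinib values of 37.1 and 0, 10.0 and 0, 30.1 and 0 and 38.1 and 0 in replicates 1 and 2, so that without replicate 2 CDC45 changed by -4.42, C11orf82 by -4.57 and HIST1H4C by -4.36. Of 12 replication-dependent histone genes, 0 rose and 12 fell, with 0 not passing (0 and 12 adjusted over the list alone, median -3.85, camera adjusted p = 3.78e-07). Of 10 histones with polyadenylated transcripts, 0 rose and 8 fell, with 2 not passing (0 and 9 adjusted over the list alone, median -1.92, camera adjusted p = 2.43e-06). HIST1H2BF changed by -3.83 ± 0.13 and HIST1H1C by -2.94 ± 0.083.

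All 17 genes of nucleolar ribosome biogenesis fell (17 adjusted over the list alone, median -2.10, camera adjusted p = 1.74e-09), among them NCL (-2.23 ± 0.068) and NPM1 (-1.51 ± 0.058). Of 21 cytosolic ribosomal proteins, 1 rose and 15 fell, with 5 not passing (1 and 15 adjusted over the list alone, median -0.28, camera adjusted p = 0.00219, adjusted p = 0.15 with an estimated correlation). Glycolysis genes were lower, with ENO1 at -1.83 ± 0.087 and LDHA at -1.45 ± 0.081. Of 17 measured, 0 rose and 13 fell, with 4 not passing (0 and 13 adjusted over the list alone, median -0.86, camera adjusted p = 7.39e-06). Of 11 heat shock genes, 1 rose and 10 fell, with 0 not passing (1 and 10 adjusted over the list alone, median -1.16, camera adjusted p = 6.44e-05). HSP90AA1 changed by -1.89 ± 0.057 and the mitochondrial chaperonin HSPD1 by -2.10 ± 0.074.

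Of 20 pigmentation and melanocyte lineage genes, 19 rose and 1 fell, with 0 not passing (19 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 8.58e-11). MITF, the lineage transcription factor, changed by 1.04 ± 0.054, the melanosome protein GPNMB by 1.68 ± 0.056, and OCA2 by 1.79 ± 0.073. Other large rises were the potassium channel gene KCNJ13 (7.18 ± 0.88), the chemokine CXCL12 (5.46 ± 0.27), UBD (6.36 ± 0.93), ADAMTS14 (6.08 ± 0.90), TRPM8 (5.65 ± 1.10), FBXL7 (5.57 ± 0.72), TCN1 (5.35 ± 0.65) and PCSK2 (5.33 ± 0.35). VWF, an endothelial marker, rose from 1.2 and 1.58 to 144 and 85.4, while the endothelial markers PECAM1, CDH5 and KDR had means of at most 1.53 in every group.

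Of 21 cholesterol synthesis genes, 14 rose and 1 fell, with 6 not passing (15 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 4.33e-05). FDFT1 changed by 1.65 ± 0.054 and HMGCS1 by 1.67 ± 0.09. Of 24 lysosome genes, 14 rose and 2 fell, with 8 not passing (15 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 0.000789). Of 15 MHC class I genes, 9 rose and 1 fell, with 5 not passing (9 and 1 adjusted over the list alone, median 0.58, camera adjusted p = 0.00138). TAPBP, a peptide loading factor, changed by 1.14 ± 0.051. Of 22 PI3K/AKT components, 13 rose and 2 fell, with 7 not passing (13 and 2 adjusted over the list alone, median 0.42, camera adjusted p = 0.000876). The adaptor IRS2 changed by 1.37 ± 0.065. Of 8 markers of class 1 uveal melanoma, the class with lower metastatic risk, 5 rose and 0 fell, with 3 not passing (5 and 0 adjusted over the list alone, median 0.39, camera adjusted p = 0.0224, adjusted p = 0.115 with an estimated correlation). For mesenchymal and matrix genes the measures differed in sign, with a median of 0.21, a mean of -0.066 and a camera direction of higher (adjusted p = 0.0161, adjusted p = 0.0948 with an estimated correlation). Of these 17 genes, 9 rose and 2 fell, 9 and 4 adjusted over the list alone.

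The other lists did not pass. Rises and falls among receptor tyrosine kinases were 9 and 4 of 20 (9 and 4 adjusted over the list alone, camera adjusted p = 0.126), with ERBB3 at 2.01 ± 0.093 and MET at 0.78 ± 0.062. They were 5 and 4 of 19 (5 and 4 adjusted over the list alone, camera adjusted p = 0.574) for YAP/TEAD targets, 4 and 4 of 17 (4 and 4 adjusted over the list alone, camera adjusted p = 0.665) for G alpha q components and 1 and 1 of 7 (1 and 1 adjusted over the list alone, camera adjusted p = 0.662) for CDK inhibitors. In the BCL2 family they were 4 and 7 of 15 (4 and 8 adjusted over the list alone, camera adjusted p = 0.707), with the pro-apoptotic BMF at 3.00 ± 0.10, and among p53 targets 3 and 7 of 15 (3 and 8 adjusted over the list alone, camera adjusted p = 0.574). The class 2 markers, of the class with higher metastatic risk, had 1 and 2 of 3 (1 and 2 adjusted over the list alone, camera adjusted p = 0.574). Rises and falls were 8 and 2 of 18 (8 and 2 adjusted over the list alone, camera adjusted p = 0.188) for histone deacetylases, 5 and 2 of 13 (5 and 3 adjusted over the list alone, camera adjusted p = 0.562) for acetyltransferases and BET proteins and 1 and 3 of 13 (1 and 1 adjusted over the list alone, camera adjusted p = 0.707) for neuronal genes. They were 2 and 2 of 16 (2 and 2 adjusted over the list alone, camera adjusted p = 0.574) for interferon-stimulated genes and 3 and 5 of 15 (3 and 5 adjusted over the list alone, camera adjusted p = 0.574) for the unfolded protein and integrated stress response. Of lists too small to test, neither of 2 MHC class II genes passed, 1 of 2 metallothioneins fell (MT2A, -4.56 ± 1.15, -2.18 without trametinib replicate 2), the cancer-testis gene SSX1 rose by 0.91 ± 0.20, and 0 mitochondrially encoded RNAs were in the table.

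Among single genes of the target pathways, MAP2K2 (MEK2) changed by -0.55 ± 0.13, YAP1 by -0.70 ± 0.08, IGF1R by -0.64 ± 0.15, GNA11 by -0.74 ± 0.17, BAP1 by -0.43 ± 0.13, HDAC2 by -0.45 ± 0.16 and CDKN1A, which encodes the CDK inhibitor p21, by -0.37 ± 0.075. MAP2K1 (-0.20 ± 0.18), GNAQ (0.26 ± 0.20), HDAC1 (-0.12 ± 0.15) and HDAC3 (-0.33 ± 0.18) did not pass. ROR1, a receptor tyrosine kinase, was at 103 and 117 in vehicle and 76.2 and 14.1 with trametinib (-1.70 ± 0.63, limma adjusted p = 0.0484). Its call ended without vehicle replicate 1 (-1.79) or 2 (-1.61), trametinib replicate 2 (-0.52), panobinostat replicate 1 (-1.70) or 2 (-1.70) or combination replicate 1 (-1.70) or 2 (-1.70), and its change was -2.88 without trametinib replicate 1. The HDAC2 call ended without vehicle replicate 1 (-0.58) or 2 (-0.33), trametinib replicate 1 (-0.26), panobinostat replicate 1 (-0.45) or 2 (-0.45) or combination replicate 1 (-0.45) or 2 (-0.45). The BAP1 call ended without vehicle replicate 1 (-0.34) or trametinib replicate 2 (-0.26). The MAP2K2 call ended without vehicle replicate 2 (-0.43). With the other 7 libraries resampled to the read multiplicity of trametinib replicate 2 (matched complexity), 1102 genes rose and 1402 fell. In simulated data with 100 genes changed 2-fold and 100 changed 4-fold, limma called 99 of 13120 unchanged genes (0.755%), 40.1% of its calls. Both shares hold for that number of changed genes, not for the 6797 calls here.

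**Figure D2:**
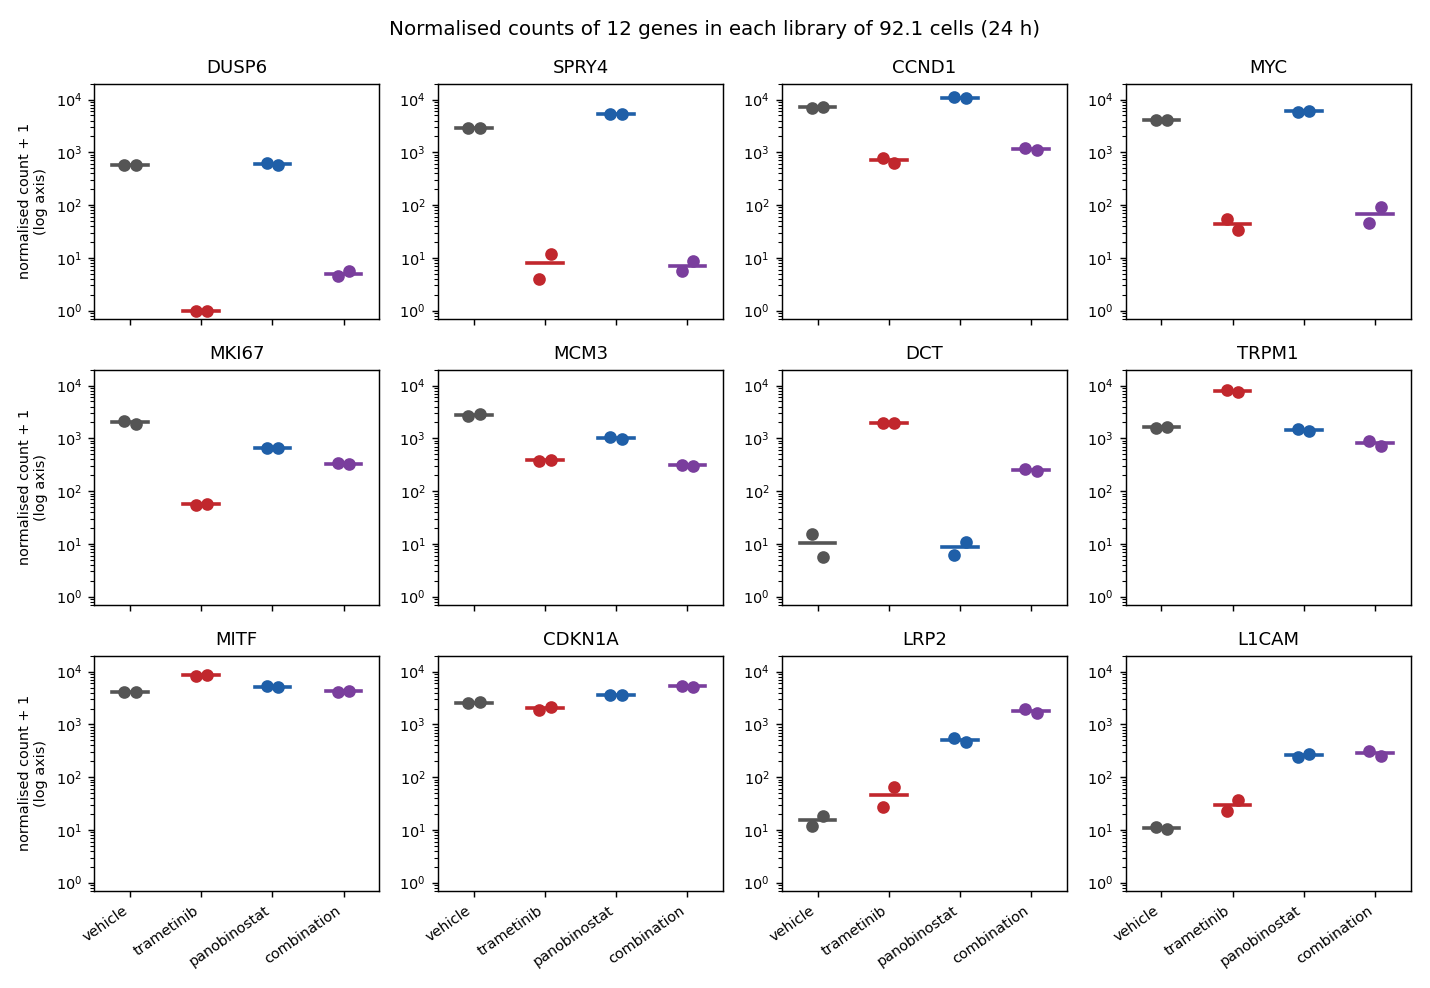
Normalised count + 1 (log axis) of 12 genes in each library (points) with the mean of the 2 libraries per group (lines). DUSP6 lies at 0 in both trametinib libraries and at means of 572 in vehicle and 605 with panobinostat, and DCT rises with trametinib from 9.6 to 1948.

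Panobinostat against vehicle shows the drug's effect and any difference in handling. Mitosis and DNA replication genes fell, single genes near 0 in vehicle rose, and no measured gene of ERK pathway output passed as lower. Of 12 replication-dependent histones 8 fell, a list call that ended with an estimated correlation (adjusted p = 0.0803), as did the call for neuronal genes, of which 5 of 13 rose (adjusted p = 0.0818). LRP2, an endocytic receptor, rose from 10.8 and 17.4 to 548 and 473, and the adhesion molecule L1CAM from 10.2 and 9.5 to 244 and 274. By limma, 1994 genes rose and 2075 fell, of which 790 and 541 changed by at least 2-fold. At matched complexity 352 rose and 290 fell. Low genes tended to rise in general, with 107 higher and 12 lower (median log2 change 0.39) among the 2096 tested genes with a mean of 10 to 50 over all libraries.

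The 10 largest rises were CTNNA2 (5.55 ± 0.93), the vesicular glutamate transporter SLC17A7 (5.44 ± 0.51), LRP2 (5.11 ± 0.40), NOX5 (4.98 ± 1.57), NFASC (4.69 ± 0.71), the synaptic vesicle protein SYN1 (4.59 ± 1.40), L1CAM (4.58 ± 0.35), SCARA5 (4.43 ± 0.89), the neuronal splicing factor NOVA2 (4.42 ± 0.55) and GALNTL1 (4.37 ± 0.93), with limma adjusted p from 3.04e-05 to 0.0384. Of 13 measured neuronal genes, 5 rose and 0 fell, with 8 not passing (5 and 0 adjusted over the list alone, median 1.69, camera adjusted p = 0.00906, adjusted p = 0.0818 with an estimated correlation). VGF changed by 1.69 ± 0.14 and MAPT by 3.85 ± 1.17. Some of these calls ended when 1 library was left out. NOX5 no longer passed without vehicle replicate 1 (5.45) or 2 (4.52), panobinostat replicate 1 (5.12) or 2 (4.85) or combination replicate 1 (4.98) or 2 (4.98). SYN1 did not pass without vehicle replicate 1 (3.58) or 2 (5.61), panobinostat replicate 1 (4.62) or 2 (4.56) or combination replicate 1 (4.59) or 2 (4.59). MAPT did not pass without vehicle replicate 1 (3.68) or 2 (4.02), panobinostat replicate 1 (3.60) or 2 (4.09) or combination replicate 1 (3.85) or 2 (3.85). SCARA5 no longer passed without vehicle replicate 2 (4.08) or panobinostat replicate 1 (4.01). GALNTL1 did not pass without vehicle replicate 1 (4.26) or panobinostat replicate 2 (3.90). Of 17 mesenchymal and matrix genes, 9 rose and 0 fell, with 8 not passing (9 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 0.00325, adjusted p = 0.0818 with an estimated correlation). FN1 (fibronectin) changed by 1.14 ± 0.085.

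Of 12 replication-dependent histone genes, 0 rose and 8 fell, with 4 not passing (0 and 9 adjusted over the list alone, median -2.50, camera adjusted p = 4.42e-08, adjusted p = 0.0803 with an estimated correlation). Of 10 with polyadenylated transcripts, 0 rose and 8 fell, with 2 not passing (0 and 8 adjusted over the list alone, median -1.21, camera adjusted p = 9.88e-07). HIST1H2AB, HIST1H2AK, HIST1H2BJ, HIST1H3H, HIST1H2BF, HIST1H3B and HIST2H3D were 7 of the 10 largest falls, from -4.72 ± 0.68 for HIST1H2AB to -2.81 ± 0.50 for HIST2H3D. The others were TXNDC5 (-3.37 ± 0.94), C16orf59 (-3.22 ± 0.72) and FAM111B (-2.79 ± 0.48), of which TXNDC5 no longer passed without vehicle replicate 1 (-3.42) or 2 (-3.31) or panobinostat replicate 1 (-3.64) or 2 (-3.09). C16orf59 did not pass without vehicle replicate 1 (-3.18) or 2 (-3.26) or panobinostat replicate 1 (-3.23) or 2 (-3.21). Of 25 mitosis genes, 0 rose and 23 fell, with 2 not passing (0 and 24 adjusted over the list alone, median -1.40, camera adjusted p = 2.22e-13). Of 30 DNA replication genes, 0 rose and 24 fell, with 6 not passing (0 and 26 adjusted over the list alone, median -1.99, camera adjusted p = 4.34e-15). MKI67 changed by -1.63 ± 0.12, FOXM1 by -1.51 ± 0.085 and the licensing factor CDT1 by -2.59 ± 0.22. Of 17 nucleolar genes, 0 rose and 11 fell, with 6 not passing (0 and 11 adjusted over the list alone, median -0.82, camera adjusted p = 1.33e-06). NPM1 changed by -0.90 ± 0.058.

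Of 21 genes of ERK pathway output, 5 rose and 0 fell, with 16 not passing (5 and 0 adjusted over the list alone, median 0.60, camera adjusted p = 0.00306, adjusted p = 0.0818 with an estimated correlation). CCND1 changed by 0.60 ± 0.10 and PHLDA1 by 1.42 ± 0.088, while DUSP6 (0.08 ± 0.44), SPRY4 (0.88 ± 0.44) and ETV5 (0.54 ± 0.25) did not pass. Of 22 PI3K/AKT components, 11 rose and 3 fell, with 8 not passing (11 and 4 adjusted over the list alone, median 0.22, camera adjusted p = 0.0119, adjusted p = 0.0818 with an estimated correlation). FOXO1 changed by 1.81 ± 0.10. Of 13 acetyltransferases and BET proteins, 0 rose and 7 fell, with 6 not passing (0 and 7 adjusted over the list alone, median -0.35, camera adjusted p = 0.0099, adjusted p = 0.0818 with an estimated correlation). BRD2 changed by -0.51 ± 0.058. Of the 18 deacetylases, HDAC1 to HDAC11 and the sirtuins SIRT1 to SIRT7, rises and falls numbered 2 and 4 of 18 (3 and 4 adjusted over the list alone, camera adjusted p = 0.979), with HDAC9 at 1.31 ± 0.10. HDAC1 (0.20 ± 0.15), HDAC2 (-0.34 ± 0.16) and HDAC3 (-0.031 ± 0.18) did not pass.

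Of 15 MHC class I genes, 8 rose and 2 fell, with 5 not passing (8 and 3 adjusted over the list alone, median 0.23, camera adjusted p = 0.0404, adjusted p = 0.139 with an estimated correlation). HLA-B changed by 0.73 ± 0.053. Of 24 lysosome genes, 10 rose and 2 fell, with 12 not passing (10 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.00998, adjusted p = 0.0818 with an estimated correlation). Of 8 class 1 markers, 4 rose and 1 fell, with 3 not passing (4 and 1 adjusted over the list alone, median 0.50, camera adjusted p = 0.0305, adjusted p = 0.137 with an estimated correlation). Falls prevailed in glycolysis, where 2 rose and 11 fell, with 4 not passing (2 and 12 adjusted over the list alone, median -0.42, camera adjusted p = 0.00227, adjusted p = 0.0818 with an estimated correlation). In heat shock genes, 0 rose and 6 fell, with 5 not passing (0 and 6 adjusted over the list alone, median -0.44, camera adjusted p = 0.000188, adjusted p = 0.0803 with an estimated correlation). Of 21 cholesterol synthesis genes, 1 rose and 7 fell, with 13 not passing (2 and 9 adjusted over the list alone, median -0.20, camera adjusted p = 0.0305, adjusted p = 0.16 with an estimated correlation). Of 21 cytosolic ribosomal proteins, 0 rose and 7 fell, with 14 not passing (0 and 7 adjusted over the list alone, median -0.084, camera adjusted p = 0.0187, adjusted p = 0.226 with an estimated correlation). The list call ended for MHC class I without trametinib replicate 1 (0.23) or 2 (0.23) or combination replicate 1 (0.23) or 2 (0.23) and for cytosolic ribosomal proteins without vehicle replicate 2 (-0.10) or panobinostat replicate 2 (-0.067). Among single genes, MITF changed by 0.34 ± 0.054, CDKN1A by 0.48 ± 0.075, IGF1R by 0.81 ± 0.15, YAP1 by -0.26 ± 0.08, GNA11 by -0.75 ± 0.17 and MAP2K2 by -0.66 ± 0.13. YAP1 no longer passed without vehicle replicate 1 (-0.23) or 2 (-0.29), panobinostat replicate 1 (-0.31) or 2 (-0.22) or combination replicate 1 (-0.26) or 2 (-0.26). GNA11 did not pass without vehicle replicate 1 (-0.79) or 2 (-0.71) or panobinostat replicate 1 (-0.73) or 2 (-0.78). MAP2K2 did not pass without vehicle replicate 2 (-0.54) or panobinostat replicate 2 (-0.60). Pigmentation genes had rises and falls of 6 and 6 of 20 (6 and 7 adjusted over the list alone, camera adjusted p = 0.857).

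The number of panobinostat calls depended on the trametinib libraries through the pooled spread, with 3368 rises and 3436 falls without trametinib replicate 2, 3359 and 3430 without trametinib replicate 1, and 3567 and 3768 in a fit of only the 4 libraries compared. They fell to 1076 and 918 without vehicle replicate 1, 1029 and 942 without vehicle replicate 2, 1064 and 1084 without panobinostat replicate 1, and 1050 and 1106 without panobinostat replicate 2. The panobinostat and combination libraries were deposited later, without a listed genome build. Any difference in handling from the other libraries cannot be told apart from panobinostat in the comparisons that cross the sets.

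In the combination against vehicle, ERK pathway output fell as with trametinib, mitosis and DNA replication genes fell as with either drug, and single genes such as LRP2 rose as with panobinostat. Of the 1994 genes that rose with panobinostat, 1652 also rose in the combination and 72 fell, where independent lists would share 488 rises. Part of the excess may come from the shared controls or set. Neuronal genes had rises and falls of 6 and 1 of 13 (6 and 1 adjusted over the list alone, camera adjusted p = 0.131) against vehicle, with a median of 0.63, and 1 and 1 of 13 (1 and 1 adjusted over the list alone, camera adjusted p = 0.938) against panobinostat. SPRY4 was at 4.68 and 7.61 against 2838 and 2849 in vehicle, and MYC, a growth-promoting transcription factor, at 44.5 and 89.8 against 4021 and 4133. LRP2 reached 1960 and 1657, and CDKN1A rose from 2564 and 2601 to 5237 and 5223. By limma, 3259 genes rose and 3403 fell, 1702 and 1583 of them by at least 2-fold, and at matched complexity 1212 rose and 1504 fell.

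Of 21 genes of ERK pathway output, 1 rose and 15 fell, with 5 not passing (2 and 15 adjusted over the list alone, median -2.36, camera adjusted p = 1.01e-06). SPRY4 changed by -8.67 ± 0.44, DUSP6 by -6.84 ± 0.44, MYC by -5.99 ± 0.30, ETV5 by -5.34 ± 0.25, ETV4 by -5.18 ± 0.25, SPRY2 by -5.31 ± 0.54 and CCND1 by -2.64 ± 0.10. Other large falls were SH3TC2 (-6.06 ± 0.47), the metabolic kinase PDK4 (-5.43 ± 0.90), HIST1H2BJ (-5.17 ± 0.38) and the gap junction gene GJB1, at 0 in both libraries and at least 18.4-fold lower. Of 25 mitosis genes, 0 rose and 23 fell, with 2 not passing (0 and 24 adjusted over the list alone, median -2.10, camera adjusted p = 5.4e-11). Of 30 DNA replication genes, 0 rose and 29 fell, with 1 not passing (0 and 29 adjusted over the list alone, median -3.35, camera adjusted p = 9.16e-14). MKI67 changed by -2.59 ± 0.12 and MCM3 by -3.15 ± 0.10. Of 12 replication-dependent histones, 0 rose and 11 fell, with 1 not passing (0 and 11 adjusted over the list alone, median -2.80, camera adjusted p = 1.02e-05, adjusted p = 0.076 with an estimated correlation). Of 10 with polyadenylated transcripts, 1 rose and 8 fell, with 1 not passing (1 and 8 adjusted over the list alone, median -1.07, camera adjusted p = 0.0011, adjusted p = 0.076 with an estimated correlation). All 17 nucleolar genes fell (17 adjusted over the list alone, median -2.46, camera adjusted p = 8.66e-11), with NOLC1 at -2.60 ± 0.08.

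The largest rises were SEPP1 (7.50 ± 0.72), the neuronal migration gene DCX (7.24 ± 0.83), LRP2 (6.93 ± 0.40), TCN1 (6.80 ± 0.65), the neuropeptide NTS (6.79 ± 0.81), SLC3A1 (6.69 ± 0.49), TRPM8 (6.63 ± 1.10), DAPL1 (6.38 ± 0.45), DACH1 (6.17 ± 1.00) and EPHA3 (6.16 ± 1.00). Of 7 CDK inhibitors, 4 rose and 0 fell, with 3 not passing (4 and 0 adjusted over the list alone, median 0.83, camera adjusted p = 0.0167, adjusted p = 0.119 with an estimated correlation). CDKN1A changed by 1.02 ± 0.075 and CDKN1C by 5.08 ± 0.53. Of 19 YAP/TEAD targets, 12 rose and 3 fell, with 4 not passing (12 and 3 adjusted over the list alone, median 0.58, camera adjusted p = 0.0167, adjusted p = 0.163 with an estimated correlation). CTGF changed by 2.08 ± 0.28. Of 17 mesenchymal and matrix genes, 10 rose and 0 fell, with 7 not passing (10 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 0.00193, adjusted p = 0.076 with an estimated correlation). Of 22 PI3K/AKT components, 13 rose and 3 fell, with 6 not passing (13 and 4 adjusted over the list alone, median 0.36, camera adjusted p = 0.00504, adjusted p = 0.076 with an estimated correlation). IRS2 changed by 2.66 ± 0.065. BMF of the BCL2 family changed by 3.98 ± 0.10 and BCL2L11, which encodes the pro-apoptotic BIM, by 2.21 ± 0.27. Rises and falls in that family were 6 and 4 of 15 (6 and 4 adjusted over the list alone, camera adjusted p = 0.761).

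Of 15 MHC class I genes, 9 rose and 2 fell, with 4 not passing (9 and 2 adjusted over the list alone, median 0.65, camera adjusted p = 0.0154, adjusted p = 0.106 with an estimated correlation). Of 24 lysosome genes, 15 rose and 3 fell, with 6 not passing (15 and 3 adjusted over the list alone, median 0.39, camera adjusted p = 0.00389, adjusted p = 0.076 with an estimated correlation). Of 8 class 1 markers, 4 rose and 1 fell, with 3 not passing (4 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.0167, adjusted p = 0.115 with an estimated correlation). SATB1 changed by 2.32 ± 0.11. In glycolysis, 0 rose and 16 fell, with 1 not passing (0 and 16 adjusted over the list alone, median -0.75, camera adjusted p = 1.01e-06, adjusted p = 0.0518 with an estimated correlation). In heat shock genes, 1 rose and 7 fell, with 3 not passing (1 and 8 adjusted over the list alone, median -1.20, camera adjusted p = 0.000691, adjusted p = 0.076 with an estimated correlation). Of 21 cytosolic ribosomal proteins, 0 rose and 15 fell, with 6 not passing (0 and 16 adjusted over the list alone, median -0.21, camera adjusted p = 0.0011, adjusted p = 0.119 with an estimated correlation). Of 13 acetyltransferases and BET proteins, 1 rose and 7 fell, with 5 not passing (1 and 7 adjusted over the list alone, median -0.35, camera adjusted p = 0.0302, adjusted p = 0.119 with an estimated correlation). Pigmentation genes had rises and falls of 8 and 6 of 20 (8 and 6 adjusted over the list alone, camera adjusted p = 0.303), and MITF (0.05 ± 0.054), at 4184 and 4336, did not pass. The fibroblast marker COL1A1 rose from a mean of 141 in vehicle to 691 in the combination, 666 with trametinib and 551 with panobinostat. The fibroblast markers LUM (257 to 547, 1.08 ± 0.19, limma adjusted p = 0.0012) and COL3A1 (0 to 19.7, below the mean at which genes were tested) were also higher in the combination, while THY1 and FAP were at 0 in all groups.

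**Figure D3:**
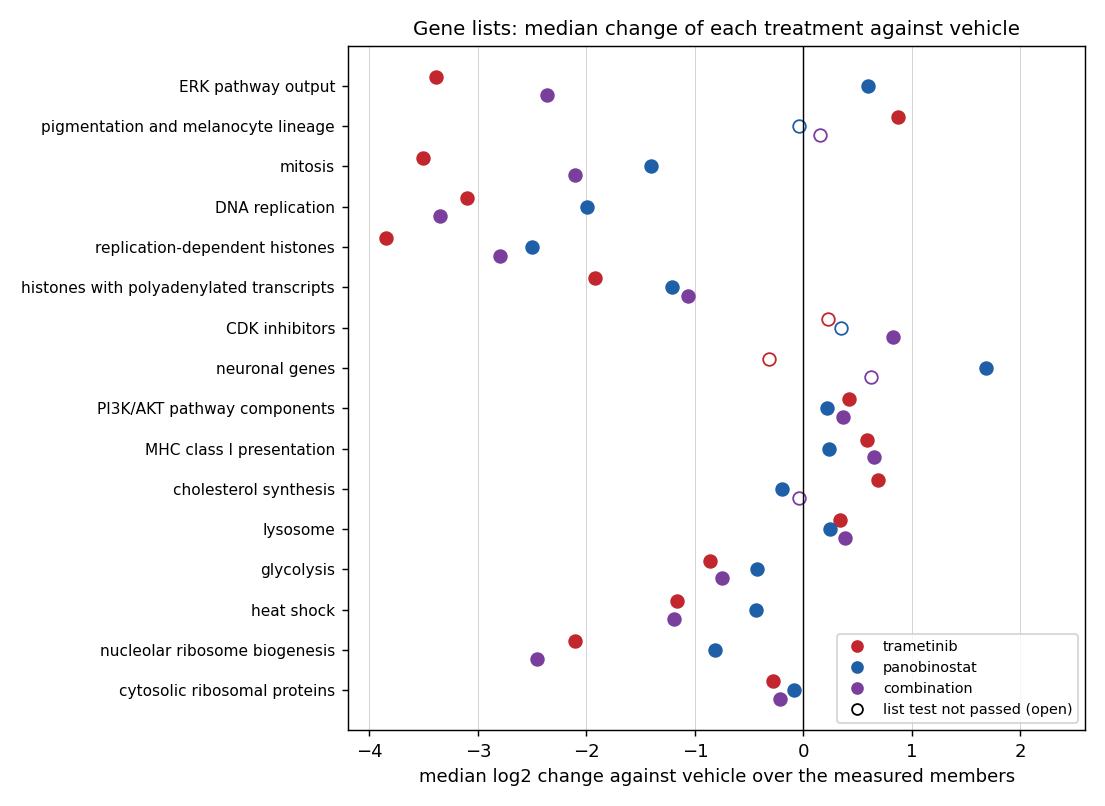
Median log2 change against vehicle over the measured members of 16 lists for trametinib (red), panobinostat (blue) and the combination (purple), with open circles where the camera test at a preset correlation did not pass. ERK pathway output lies at -3.39 with trametinib, 0.60 with panobinostat and -2.36 in the combination.

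The combination against trametinib adds panobinostat, with any set difference, to MEK inhibition. Pigmentation and cholesterol synthesis genes were lower than with trametinib alone, and mitosis genes were higher. Single genes at 0 in both trametinib libraries, which had the most genes at 0, were detected in the combination, and low genes rose in general, with 302 higher and 48 lower (median log2 change 0.88) among the 2096 with a mean of 10 to 50. All list calls of this comparison ended with an estimated correlation (adjusted p = 0.0669 for each of pigmentation, cholesterol synthesis and mitosis). TRPM1, a melanocyte channel gene regulated by MITF, stood at 8151 and 7512 with trametinib and 896 and 699.8 in the combination. MKI67 stood at 54.2 and 56.3 with trametinib, 335 and 327 in the combination and 2106 and 1906 in vehicle. By limma, 2343 genes rose and 2020 fell, 1232 and 441 of them by at least 2-fold. The balance turned in genes with a mean of at least 500, with 974 higher and 1409 lower, and at matched complexity the numbers were 487 and 486. In simulation limma called 112 of 13120 unchanged genes (0.854%), which again holds only there.

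Of 20 pigmentation genes, 2 rose and 15 fell, with 3 not passing (2 and 15 adjusted over the list alone, median -0.96, camera adjusted p = 2.81e-09, adjusted p = 0.0669 with an estimated correlation). TRPM1 changed by -3.30 ± 0.11, SLC45A2 by -2.26 ± 0.10 and MITF by -0.99 ± 0.054. Of 21 cholesterol synthesis genes, 0 rose and 16 fell, with 5 not passing (0 and 17 adjusted over the list alone, median -0.57, camera adjusted p = 4.89e-07, adjusted p = 0.0669 with an estimated correlation). HMGCS1 changed by -1.20 ± 0.09. Of 13 acetyltransferases and BET proteins, 2 rose and 10 fell, with 1 not passing (2 and 10 adjusted over the list alone, median -0.48, camera adjusted p = 0.00087, adjusted p = 0.112 with an estimated correlation). The largest falls were ADAMTS14 (-5.94 ± 0.90), LDB3 (-4.24 ± 0.49), ERVFRD-1 (-3.96 ± 1.32), the neurotrophin receptor NTRK2 (-3.91 ± 0.76), CNTN2 (-3.80 ± 0.90), CYP19A1 (-3.67 ± 0.66), TRPM1, ZNF469 (-3.07 ± 0.59), GALNT3 (-3.05 ± 0.23) and DGKI (-2.98 ± 0.12). ERVFRD-1 no longer passed without vehicle replicate 1 (-3.96) or 2 (-3.96), panobinostat replicate 1 (-3.96) or 2 (-3.96) or combination replicate 2 (-2.20). CNTN2 did not pass without combination replicate 1 (-3.25), and NTRK2 changed by -2.64 without combination replicate 1.

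Of 25 mitosis genes, 20 rose and 0 fell, with 5 not passing (23 and 0 adjusted over the list alone, median 1.57, camera adjusted p = 5.69e-10, adjusted p = 0.0669 with an estimated correlation). MKI67 changed by 2.56 ± 0.12 and CENPF by 2.75 ± 0.16. The DNA replication list did not pass, with rises and falls of 3 and 2 of 30 (3 and 1 adjusted over the list alone, camera adjusted p = 0.751). Of 12 replication-dependent histones, 8 rose and 0 fell, with 4 not passing (8 and 0 adjusted over the list alone, median 1.08, camera adjusted p = 0.00087, adjusted p = 0.18 with an estimated correlation). Of 10 with polyadenylated transcripts, 6 rose and 0 fell, with 4 not passing (6 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 0.000948, adjusted p = 0.128 with an estimated correlation). HIST1H1C changed by 1.94 ± 0.083. Of 15 p53 targets, 8 rose and 1 fell, with 6 not passing (9 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 0.00545, adjusted p = 0.132 with an estimated correlation). MDM2, a p53 regulator, changed by 0.96 ± 0.077. Of 7 CDK inhibitors, 3 rose and 0 fell, with 4 not passing (3 and 0 adjusted over the list alone, median 0.73, camera adjusted p = 0.0303, adjusted p = 0.2 with an estimated correlation). CDKN1A changed by 1.39 ± 0.075. The CDK inhibitor call ended without trametinib replicate 1 (0.42) or combination replicate 1 (0.92).

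Of 13 neuronal genes, 7 rose and 0 fell, with 6 not passing (7 and 0 adjusted over the list alone, median 1.49, camera adjusted p = 0.019, adjusted p = 0.16 with an estimated correlation). Of 19 YAP/TEAD targets, 9 rose and 2 fell, with 8 not passing (10 and 2 adjusted over the list alone, median 0.67, camera adjusted p = 0.0138, adjusted p = 0.2 with an estimated correlation). Of 21 genes of ERK pathway output, 10 rose and 1 fell, with 10 not passing (11 and 2 adjusted over the list alone, median 0.95, camera adjusted p = 0.00774, adjusted p = 0.132 with an estimated correlation). CCND1 changed by 0.71 ± 0.10 and ETV5 by -1.63 ± 0.25, and SPRY4 (0.0089 ± 0.44) did not pass. DUSP6 was at 3.51 and 4.56 in the combination, 3 reads per library, and at 0 with trametinib, so no fold is given. The largest rises were NTS (7.79 ± 0.81), DCX (7.08 ± 0.83), EPHA3 (6.88 ± 1.00) and MAP7 (6.79 ± 0.78). CADM1, VGLL3, DACH1, HSPB3, ADAMTS5 and CRIP2 were at 0 with trametinib. In the combination they were 52-, 47.7-, 45.8-, 36.8-, 35.9- and 33.5-fold above the floor. IGF1R changed by 1.17 ± 0.15, YAP1 by 0.51 ± 0.08 and MET by -2.34 ± 0.062, while HDAC1, HDAC2 and HDAC3 (0.28 ± 0.15, -0.14 ± 0.16 and 0.18 ± 0.18) did not pass. A fit of only the 4 libraries gave 1148 rises and 1108 falls, and leaving out trametinib replicate 1 gave 4238 and 3145. Without combination replicate 1 the numbers were 1243 and 1267, and without combination replicate 2 1250 and 1240.

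The combination against panobinostat shows what MEK inhibition does when deacetylases are inhibited. ERK pathway output fell, DNA replication and ribosome biogenesis genes fell further than with panobinostat alone, and the melanocyte gene DCT rose from 5.1 and 10.1 to 258 and 236. Pigmentation genes as a list did not pass, with rises and falls of 10 and 6 of 20 (10 and 8 adjusted over the list alone, camera adjusted p = 0.222) and a median of 0.18. SPRY4 stood at 5265 and 5217 with panobinostat and 4.68 and 7.61 in the combination. By limma, 1451 genes rose and 1740 fell, 415 and 541 of them by at least 2-fold, and at matched complexity 311 rose and 464 fell.

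Of 21 genes of ERK pathway output, 0 rose and 15 fell, with 6 not passing (0 and 15 adjusted over the list alone, median -3.24, camera adjusted p = 2.27e-15). SPRY4 changed by -9.55 ± 0.44, DUSP6 by -6.92 ± 0.44, MYC by -6.55 ± 0.30, ETV5 by -5.88 ± 0.25, ETV4 by -5.85 ± 0.25 and CCND1 by -3.24 ± 0.10. Other large falls were the receptor ALK (-6.52 ± 1.06), SH3TC2 (-5.81 ± 0.47) and PDK4 (-5.80 ± 0.90). GJB1 and NOX5 were at 0 in both combination libraries and at least 33.9-fold and 19.2-fold lower, the NOX5 call ending without panobinostat replicate 1 (-6.42) or 2 (-6.16) or combination replicate 1 (-6.29) or 2 (-6.29). Of 17 nucleolar genes, 0 rose and 16 fell, with 1 not passing (0 and 16 adjusted over the list alone, median -1.63, camera adjusted p = 4.35e-14). Of 30 DNA replication genes, 0 rose and 18 fell, with 12 not passing (0 and 21 adjusted over the list alone, median -1.34, camera adjusted p = 6.38e-10). Of 25 mitosis genes, 0 rose and 8 fell, with 17 not passing (0 and 13 adjusted over the list alone, median -0.55, camera adjusted p = 3.13e-05, adjusted p = 0.104 with an estimated correlation). NCL changed by -1.34 ± 0.068, MCM3 by -1.70 ± 0.10 and MKI67 by -0.96 ± 0.12. In glycolysis, 0 rose and 11 fell, with 6 not passing (0 and 12 adjusted over the list alone, median -0.47, camera adjusted p = 2.39e-06, adjusted p = 0.0707 with an estimated correlation). In heat shock genes, 1 rose and 6 fell, with 4 not passing (1 and 6 adjusted over the list alone, median -0.78, camera adjusted p = 0.00069, adjusted p = 0.104 with an estimated correlation). In cytosolic ribosomal proteins, 0 rose and 2 fell, with 19 not passing (0 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 0.018, adjusted p = 0.232 with an estimated correlation). The last call ended without panobinostat replicate 1 (-0.12) or combination replicate 2 (-0.11).

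The largest rises were KCNJ13 (5.80 ± 0.88), TRPM8 (5.48 ± 1.10), DIO2 (5.13 ± 0.61), RASGEF1B (5.11 ± 1.50), DCT (4.91 ± 0.48), C5orf46 (4.81 ± 1.16), SFRP4 (4.73 ± 1.48), UBD (4.52 ± 0.93), ZNF536 (4.33 ± 0.56) and SEPP1 (4.24 ± 0.72). RASGEF1B no longer passed without vehicle replicate 1 (5.11) or 2 (5.11), panobinostat replicate 1 (5.92) or 2 (4.31) or combination replicate 1 (5.32) or 2 (4.91). SFRP4 did not pass without vehicle replicate 1 (4.73) or 2 (4.73), panobinostat replicate 1 (5.90) or 2 (3.55) or combination replicate 1 (5.01) or 2 (4.44). C5orf46 no longer passed without panobinostat replicate 2 (4.01) or combination replicate 1 (4.37) or 2 (5.25). TRPM8 did not pass without combination replicate 1 (5.46) or 2 (5.51). UBD did not pass without combination replicate 2 (4.06), and TRPM8 changed by 3.57 without panobinostat replicate 1. Of 7 CDK inhibitors, 5 rose and 0 fell, with 2 not passing (5 and 0 adjusted over the list alone, median 0.54, camera adjusted p = 0.00512, adjusted p = 0.129 with an estimated correlation). Of 15 MHC class I genes, 6 rose and 2 fell, with 7 not passing (8 and 2 adjusted over the list alone, median 0.32, camera adjusted p = 0.012, adjusted p = 0.129 with an estimated correlation). Of 22 PI3K/AKT components, 9 rose and 2 fell, with 11 not passing (10 and 4 adjusted over the list alone, median 0.22, camera adjusted p = 0.018, adjusted p = 0.129 with an estimated correlation). Of 21 cholesterol synthesis genes, 11 rose and 3 fell, with 7 not passing (11 and 3 adjusted over the list alone, median 0.34, camera adjusted p = 0.013, adjusted p = 0.143 with an estimated correlation). Of 24 lysosome genes, 7 rose and 2 fell, with 15 not passing (7 and 2 adjusted over the list alone, median 0.14, camera adjusted p = 0.0332, adjusted p = 0.143 with an estimated correlation). BMF changed by 2.52 ± 0.10, CDKN1A by 0.54 ± 0.075 and MITF by -0.29 ± 0.054. Leaving out trametinib replicate 2, which is in neither group, gave 2758 rises and 2989 falls, and leaving out trametinib replicate 1 gave 2758 and 2981. The numbers fell to 757 and 929 without panobinostat replicate 1, 766 and 962 without panobinostat replicate 2, 741 and 1091 without combination replicate 1, and 714 and 1060 without combination replicate 2.

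The interaction tests whether one drug's effect differed when the other was present. The cell cycle fell less in the combination than the sum of the single-drug changes, and pigmentation genes ended lower than that sum. MKI67 had an interaction of 4.19 ± 0.18 and TRPM1 of -3.13 ± 0.16, both in log2. By limma, 1361 genes had a positive and 1204 a negative interaction, and in 2436 of these 2565 genes the interaction was opposite in sign to the trametinib effect (94.97%), and in 2065 to the panobinostat effect (80.5%). In genes with a mean of at least 500, 831 interactions were positive and 1048 negative. The trametinib libraries enter both the trametinib effect and the interaction, and the panobinostat and vehicle libraries likewise. Simulated groups with no effects gave 99.5% and 78.6% among the 2565 genes with the largest interaction over its error, so these shares alone show no opposition of the drugs.

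The median member of the mitosis, DNA replication and replication-dependent histone lists stood at 9.05%, 12% and 6.87% of vehicle with trametinib, at 37.8%, 25.1% and 17.3% with panobinostat and at 23.2%, 9.81% and 14.3% in the combination. All 25 mitosis genes had a positive interaction past the threshold (25 adjusted over the list alone, median 2.90, camera adjusted p = 5.56e-22), as did 23 of 30 DNA replication genes (26 adjusted over the list alone, median 2.19, camera adjusted p = 3.38e-14). So did 10 of 12 replication-dependent histones (12 adjusted over the list alone, median 3.63, camera adjusted p = 1.13e-10, adjusted p = 0.053 with an estimated correlation) and 9 of 10 histones with polyadenylated transcripts (9 adjusted over the list alone, median 1.86, camera adjusted p = 1.04e-10). Of 20 pigmentation genes, 16 had a negative interaction (16 adjusted over the list alone, median -0.95, camera adjusted p = 3.41e-14), MITF at -1.34 ± 0.076.

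The largest positive interactions were HIST1H4C (7.09 ± 1.78), CDC25C (6.90 ± 0.99), FAM173A (6.07 ± 1.04), KIF20B (6.05 ± 1.40) and CNKSR2 (5.87 ± 0.78), and the largest negative ones NOX5 (-7.34 ± 2.22), ADAMTS14 (-6.80 ± 1.27), ZNF469 (-5.70 ± 0.83), NTRK2 (-4.46 ± 1.07) and LDB3 (-4.38 ± 0.69). HIST1H4C no longer passed without vehicle replicate 1 (7.01) or 2 (7.16), panobinostat replicate 1 (7.28) or 2 (6.89) or combination replicate 1 (7.23) or 2 (6.94). KIF20B did not pass without vehicle replicate 1 (6.00) or 2 (6.10), panobinostat replicate 1 (5.90) or 2 (6.21) or combination replicate 1 (6.18) or 2 (5.93). NOX5 did not pass without vehicle replicate 1 (-7.80) or 2 (-6.87), panobinostat replicate 1 (-7.47) or 2 (-7.21) or combination replicate 1 (-7.34) or 2 (-7.34). NTRK2 no longer passed without vehicle replicate 1 (-4.38) or 2 (-4.55) or panobinostat replicate 1 (-4.59) or 2 (-4.34). Without trametinib replicate 2, HIST1H4C was at 4.44 and KIF20B at 3.97. ERK pathway output did not pass, with positive and negative interactions in 1 and 1 of 21 (0 and 1 adjusted over the list alone, camera adjusted p = 0.934). CCND1 was at 0.11 ± 0.14 and did not pass. CDKN1A had an interaction of 0.91 ± 0.11. Without trametinib replicate 2 there were 4688 interaction calls, without trametinib replicate 1 6215, and with the other libraries resampled to the multiplicity of trametinib replicate 2 there were 322. Without vehicle replicates 1 and 2 in turn there were 1308 and 1340, without panobinostat replicates 1392 and 1500, and without combination replicates 1562 and 1502.

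Over the 6 contrasts, 86 list tests passed at the preset correlation and 28 of them held with an estimated correlation, 13 for trametinib, 4 for panobinostat and 4 for the combination against vehicle, 0 against trametinib, 3 against panobinostat and 4 in the interaction. For trametinib these were ERK pathway output, PI3K/AKT components, pigmentation, mitosis, DNA replication, both histone lists, MHC class I, cholesterol synthesis, lysosome, glycolysis, heat shock and nucleolar genes. For panobinostat they were mitosis, DNA replication, polyadenylated histones and nucleolar genes, and for the combination ERK pathway output, mitosis, DNA replication and nucleolar genes.

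Effects were compared across the 13320 genes, which are not independent replicates. The trametinib effect without panobinostat correlated with that in its presence at r = 0.566 (Spearman 0.562), with a slope of 0.324 and the same sign in 71.7% of genes. The panobinostat effect without and with trametinib correlated at r = 0.400 (Spearman 0.334), with a slope of 0.549. The effects of trametinib and panobinostat against the same vehicle libraries correlated at r = 0.395 (Spearman 0.438), against 0.145 simulated for unchanged groups in 100 draws, and their covariance was 0.439 against 0.0258 simulated, a difference of 0.414. Of the genes that rose with trametinib, 1198 also rose with panobinostat, where independent lists would share 472, and 1431 fell with both, where 568 would be shared, and part of the excess may come from the shared controls. The signs matched in 67.5% of genes, against 55.7% simulated for unchanged groups with the same shared controls.

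**Figure D4:**
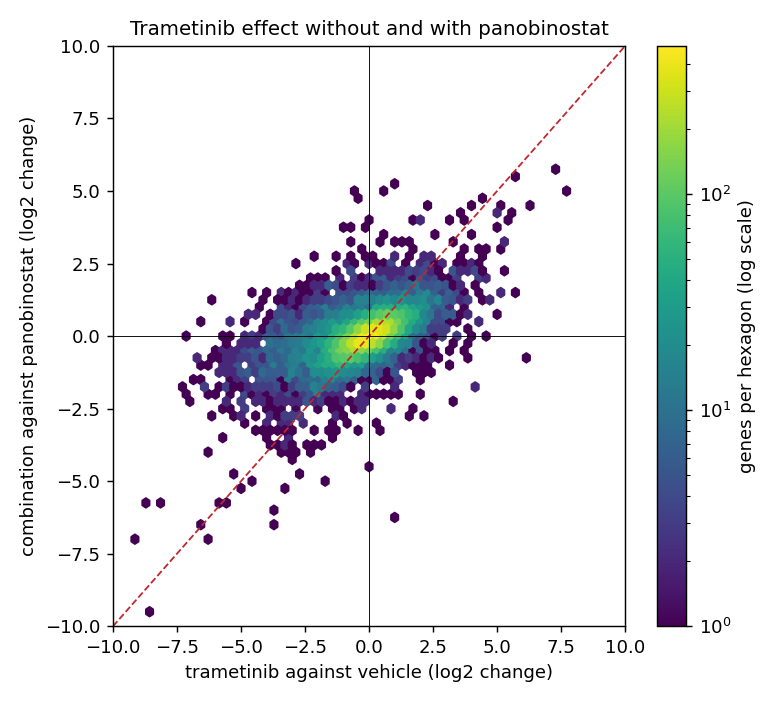
Log2 change of the combination against panobinostat (vertical) by that of trametinib against vehicle (horizontal) for 13320 genes, as hexagons coloured by the number of genes (log scale), with the line of equal change dashed. The changes correlate at r = 0.566 with a slope of 0.324.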

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

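The tests of sequencing depth and of a shift shared by the panobinostat and combination libraries were chosen after the result was seen, as was recounting calls at matched complexity.

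A test of the difference between the panobinostat effect with and without trametinib passed for 2565 genes by limma. Without vehicle replicates 1 and 2 in turn it passed for 1308 and 1340 genes, without trametinib replicates for 6215 and 4688, without panobinostat replicates for 1392 and 1500, and without combination replicates for 1562 and 1502. The median interaction of the lists that passed the camera test was 2.90 for mitosis, 2.19 for DNA replication, 3.63 for replication-dependent histones and 1.86 for histones with polyadenylated transcripts. It was 0.53 for p53 targets, 0.33 for glycolysis, 0.57 for heat shock, 0.34 for nucleolar genes and 0.16 for cytosolic ribosomal proteins, and -0.95 for pigmentation, -0.28 for MHC class I, -0.36 for cholesterol synthesis and -0.24 for lysosome. With an estimated correlation only the mitosis, DNA replication, polyadenylated histone and pigmentation calls held (adjusted p = 0.0111, 0.0111, 0.0199 and 0.0111), and the others ended, as for p53 targets (0.182) and cytosolic ribosomal proteins (0.303). The p53 call ended without vehicle replicate 2 (0.53), trametinib replicate 1 (0.52) or 2 (0.38), panobinostat replicate 2 (0.59) or combination replicate 1 (0.57) or 2 (0.48), and that of cytosolic ribosomal proteins without vehicle replicate 2 (0.12), trametinib replicate 1 (0.18) or 2 (0.17), panobinostat replicate 2 (0.14) or combination replicate 1 (0.16). The lysosome call ended without trametinib replicate 1 (-0.17) and the nucleolar call without trametinib replicate 1 (0.46).

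The single genes with the largest positive interactions were HIST1H4C (7.09), CDC25C (6.90), FAM173A (6.07), KIF20B (6.05) and CNKSR2 (5.87), and those with the largest negative ones NOX5 (-7.34), ADAMTS14 (-6.80), ZNF469 (-5.70), NTRK2 (-4.46) and LDB3 (-4.38). HIST1H4C lost its call without vehicle replicate 1 (7.01) or 2 (7.16), panobinostat replicate 1 (7.28) or 2 (6.89) or combination replicate 1 (7.23) or 2 (6.94). KIF20B lost it without vehicle replicate 1 (6.00) or 2 (6.10), panobinostat replicate 1 (5.90) or 2 (6.21) or combination replicate 1 (6.18) or 2 (5.93). NOX5 lost it without vehicle replicate 1 (-7.80) or 2 (-6.87), panobinostat replicate 1 (-7.47) or 2 (-7.21) or combination replicate 1 (-7.34) or 2 (-7.34), and NTRK2 without vehicle replicate 1 (-4.38) or 2 (-4.55) or panobinostat replicate 1 (-4.59) or 2 (-4.34).

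Trametinib replicate 2 had 5362 genes at 0 and few genes with 1 to 5 reads. Lower depth is argued against, since the library with the fewest reads, combination replicate 2, had 2601 genes at 0. When the 6 libraries without trametinib alone were drawn to the depth of trametinib replicate 2 and to molecules read 23 times each, the peak of its read numbers averaged over 5 neighbours, a median of 5783.5 genes were at 0 (5660 at 21 times, the unaveraged peak), so few molecules read many times is a candidate explanation. Genes switched off by trametinib stay open. Of 380 genes at 0 in replicate 2 with a vehicle mean of at least 20, 38 were at 0 in replicate 1. The median of the 380 there was 0.364 of vehicle, between the bounds set. The 2 explanations can act together, and no biological difference between the 2 trametinib libraries is named by the design.

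Mitosis, DNA replication and replication-dependent histone genes were higher in the combination than the sum of the single-drug log2 changes. Their median interaction was 2.57 with the other libraries resampled (2.49 at a multiplicity of 21). Few molecules in both trametinib libraries stay open, since resampling restores none lost. The pseudocount is argued against by a median of 2.54 with a pseudocount of 5. A shift shared by the panobinostat and combination libraries cancels in the interaction whatever its size, so it was not tested here. No biological explanation was tested here.

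Pigmentation genes rose with trametinib and lay lower in the combination than with trametinib. The scaling of the libraries is argued against, since the median of the combination against trametinib was -0.97 under the scaling that left it highest. A shift shared by the panobinostat and combination libraries is argued against by a median interaction of -0.95. It was -0.87 with the other libraries resampled (-0.90 at a multiplicity of 21), which leaves few molecules open too. No biological explanation was tested here, and the data hold 1 cell line, 1 time point and 1 dose of each drug.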

How the results depend on the processing

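The mean of at least 500, the library weights, the matched complexity and the multiplicity without averaging were chosen after the result was seen, and the other alternatives were planned. Numbers are genes higher and lower. In this part, changed means a count that moved by more than 1.5 times, a correlation that moved by more than its spread, or a call gained, lost or turned. Of 252 counts 79 changed, of 33 correlations 9, and of 1290 list results 94 lost their call. Of 18744 results for named genes, 17686 were the same, 202 gained a call, 854 lost it and 2 reversed, SPRY4 in the combination against trametinib at -0.79 without trametinib replicate 1 (0.80 without replicate 2) and HLA-DMB in trametinib versus vehicle at 0.96 without trametinib replicate 2 (-4.05 without replicate 1).

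At a log2 change of at least 1, the counts were 1411 and 2022 for trametinib, 790 and 541 for panobinostat and 1702 and 1583 for the combination against vehicle, 1232 and 441 against trametinib, 415 and 541 against panobinostat, and 1210 interactions. At a mean of at least 500 they were 1550 and 1622, 1081 and 1294, and 1350 and 1799 against vehicle in the same order, 974 and 1409 against trametinib and 943 and 1246 against panobinostat. At matched complexity they were 1102 and 1402, 352 and 290, 1212 and 1504, 487 and 486, and 311 and 464, with 322 interactions. With only the 4 libraries compared they were 3567 and 3768 for panobinostat, 1148 and 1108 against trametinib and 2602 and 2741 against panobinostat. With library weights they were 3596 and 3697 for panobinostat, 1151 lower against trametinib, and 2370 and 2700 against panobinostat. Leaving out 1 library gave 1029 to 3368 higher and 918 to 3436 lower for panobinostat, 1243 to 4238 and 1240 to 3145 against trametinib, 714 to 2758 and 929 to 2989 against panobinostat, and 1308 to 6215 interactions.

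The correlation of the trametinib effect with and without panobinostat was 0.615 with a pseudocount of 5, 0.667 at a mean of at least 50 and 0.446 to 0.611 with 1 library left out. That of the panobinostat effect with and without trametinib was 0.351 at a mean of at least 50 and 0.313 to 0.422 with 1 library left out. That of the trametinib and panobinostat effects was 0.467 with a pseudocount of 5, 0.499 at a mean of at least 50 and 0.297 to 0.444 with 1 library left out.

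With an estimated correlation the camera call ended, at the medians given, for these lists. With trametinib they were mesenchymal and matrix genes 0.21, cytosolic ribosomal proteins -0.28 and uveal melanoma class 1 markers 0.39. With panobinostat they were ERK pathway output 0.60, PI3K/AKT pathway components 0.22, replication-dependent histones -2.50, acetyltransferases and BET proteins -0.35, neuronal genes 1.69, MHC class I presentation 0.23, mesenchymal and matrix genes 0.52, cholesterol synthesis -0.20, lysosome 0.25, glycolysis -0.42, heat shock -0.44, cytosolic ribosomal proteins -0.084 and uveal melanoma class 1 markers 0.50. With the combination against vehicle they were YAP/TEAD targets 0.58, PI3K/AKT pathway components 0.36, CDK inhibitors 0.83, replication-dependent histones -2.80, histones with polyadenylated transcripts -1.07, acetyltransferases and BET proteins -0.35, MHC class I presentation 0.65, mesenchymal and matrix genes 0.53, lysosome 0.39, glycolysis -0.75, heat shock -1.20, cytosolic ribosomal proteins -0.21 and uveal melanoma class 1 markers 0.49. Against trametinib they were ERK pathway output 0.95, YAP/TEAD targets 0.67, pigmentation and melanocyte lineage -0.96, mitosis 1.57, CDK inhibitors 0.73, p53 targets 0.56, replication-dependent histones 1.08, histones with polyadenylated transcripts 0.53, acetyltransferases and BET proteins -0.48, neuronal genes 1.49 and cholesterol synthesis -0.57. Against panobinostat they were PI3K/AKT pathway components 0.22, mitosis -0.55, CDK inhibitors 0.54, MHC class I presentation 0.32, cholesterol synthesis 0.34, lysosome 0.14, glycolysis -0.47, heat shock -0.78 and cytosolic ribosomal proteins -0.13. In the interaction they were p53 targets 0.53, replication-dependent histones 3.63, MHC class I presentation -0.28, cholesterol synthesis -0.36, lysosome -0.24, glycolysis 0.33, heat shock 0.57, nucleolar ribosome biogenesis 0.34 and cytosolic ribosomal proteins 0.16.

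Under edgeR the call ended for cholesterol synthesis (-0.20) and cytosolic ribosomal proteins (-0.083) with panobinostat, acetyltransferases and BET proteins with the combination (-0.35), cytosolic ribosomal proteins against panobinostat (-0.13), and p53 targets (0.52), lysosome (-0.25) and cytosolic ribosomal proteins (0.16) in the interaction. Under TMM it ended for p53 targets (0.50) and cytosolic ribosomal proteins (0.13) in the interaction, with a replicate block for p53 targets (0.53), under total-count rescaling for lysosome against panobinostat (0.10), and with library weights for MHC class I with panobinostat (0.23) and cytosolic ribosomal proteins in the interaction (0.16). Over the libraries left out, medians ran 0.21 to 0.40 for mesenchymal and matrix genes with trametinib, 0.32 to 0.59 for class 1 markers, 0.20 to 0.25 for MHC class I and -0.15 to -0.067 for cytosolic ribosomal proteins with panobinostat, -0.36 to -0.23 for acetyltransferases and BET proteins with the combination, 0.42 to 1.14 for CDK inhibitors and 0.86 to 2.02 for neuronal genes against trametinib, -0.14 to -0.11 for cytosolic ribosomal proteins against panobinostat, and 0.35 to 0.61 for heat shock, 0.38 to 0.59 for p53 targets, -0.30 to -0.17 for lysosome, 0.33 to 0.51 for nucleolar genes and 0.12 to 0.20 for cytosolic ribosomal proteins in the interaction.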

Other observations

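The summaries in this part were chosen after the data were seen, except the cell type markers. Class means of genes low in vehicle stood higher in every treated group. In the 807 genes with a value of 10 to 20 in vehicle replicate 1, the ratio of the mean to that of vehicle replicate 2 was 1.96 with trametinib, 1.87 with panobinostat and 2.69 in the combination, against 1.02, 0.998 and 1.01 in the 3735 genes of the highest class. The median gene did not rise with trametinib, where the tested genes with a mean of 10 to 50 over all libraries had a median log2 change of -0.22 (212 higher and 241 lower), against 0.39 with panobinostat and 0.66 in the combination. The 75 olfactory receptor genes had 107 and 80 reads in vehicle, 160 and 247 with trametinib, 112 and 96 with panobinostat, and 180 and 117 in the combination, although the treated libraries had fewer reads in all. The receptors detected numbered 22 and 15, 15 and 9, 20 and 19, and 28 and 24 in the same order, and only trametinib replicate 2, at 9, lay below every other library.

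MALAT1, a nuclear RNA, took 4.19% and 4.23% of the reads in vehicle, 6.85% and 7.91% with trametinib, 8.29% and 8.78% with panobinostat, and 11.9% and 12.2% in the combination. The immune cell marker PTPRC had group means of at most 5.85 and the epithelial marker EPCAM of at most 9.01. The immune cell marker LYZ had means of 51.8, 38.6, 78.6 and 93.7 in vehicle, trametinib, panobinostat and the combination, and the epithelial marker KRT18 8.06, 11, 17.2 and 30.2. CD68, which melanocytic cells also express, had means of 630, 801, 1457 and 897 in the same order. LUM had means of 257, 207, 427 and 547 in the same order, COL3A1 0, 0, 2.04 and 19.7, and KRT14 3.39, 23.6, 0.504 and 38.6.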
